A study of Mus musculus with 18 samples.

How the data were processed

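Gene expression was measured in 18 libraries of 5000 to 10000 sorted cells each, with 2 to 6 ng of RNA, an RNA integrity number of at least 9.40 and a stranded total RNA kit for small inputs (SMARTer Pico), per the labels. The labels' protocol headings name nuclear extraction while their text describes sorted cells and total RNA, and whole cells were assumed. Cells were enriched with c-Kit beads and sorted on lineage markers, CD105, CD150, CD41, CD16/32 and Sca1, per the labels' protocols. Reads were aligned with STAR 2.5.2b to the mouse build mm10 (GRCm38) and counted with HTSeq, per the submitters' processing notes. The HTSeq version, its strand setting, the annotation and any filter are not given in the sources used here. The deposited count table holds whole-number read counts per gene symbol, 1 column per library, which the authors did not normalise. The deposited RPKM table holds values the authors scaled to the library total and divided by 1 number per gene. Of 21967 genes, 5325 had no count, and the 13 mitochondrial genes of the table had 0 counts.

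Library totals are the column sums of the counts, from 3541066 to 9389122, and 10782 to 13536 genes were detected. Replicate pairs differed by 7.93 to 19.8 chi-square per degree of freedom, where counting error alone gives 1. A count of 0 was read as up to 3 counts, over the group. Positions are those of GENCODE M21 on GRCm38, matched by symbol for 19580 genes, and Fam132b had no match.

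Genotypes were compared within each cell type on its 9 libraries with edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr (minimum count 10, minimum total 15) and the robust quasi-likelihood test. Cell types were compared within each genotype, and interactions of genotype and cell type tested, in 1 fit of the 6 groups on all 18 libraries, without a block. All tests were two-sided, and adjusted p are Benjamini-Hochberg values over the tested genes of a comparison with a threshold of 0.05. SE is the size of the log2 fold change divided by the square root of the F statistic. CPM are counts scaled by library total and TMM factor, and principal components were computed on log2 CPM with an offset of 0.5. Interval bounds for ratios with 1 to 3 counts are exact binomial at 95%. A gene was separated where the 3 libraries of a group all lay above the 3 others.

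There were 33 gene lists: KIT and ERK targets (feedback and immediate-early genes), erythropoietin and STAT5 targets, erythroid transcription factors, globins, haem synthesis, iron handling, red cell membrane, stem and progenitor, megakaryocyte, neutrophil and monocyte, mast cell, basophil and eosinophil, B cell, T and NK cell, island macrophage, stroma, endothelium, late erythroblast, S phase, mitosis, ribosome biogenesis, ribosomal proteins, p53 targets, BCL2 family, interferon response, amino acid and unfolded protein stress, heat shock, glycolysis and hypoxia, cholesterol synthesis, respiratory chain, mitochondrially encoded, replication histones, sex-linked genes and sort markers. Lists with at least 3 tested genes were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01 and adjusted over the lists, 31 of the 33 at most, since sex-linked genes and sort markers served as a label check and a description. Counts of changed members were adjusted over all genes and over the list alone. Symbols of the lists that the table does not hold are Ighm, Iglc1, Erfe, Hbb-b1, Hbb-b2, Ahsp, Tent5c, Epb49, Xist and Trbc2, of which Erfe, Tent5c and Epb49 are other names of Fam132b, Fam46c and Dmtn, which it holds.

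The comparisons, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names Kitl and Kit throughout. Among genes past the threshold with a mean of at least 5 CPM, separated groups and no predicted model, it names the 10 largest rises and 10 largest falls for CFU-E against PreCFU-E in FL/FL mice, 8 and 8 for each comparison with Lepr-Cre mice and 5 and 5 for KO/FL against FL/FL. Where fewer than 3 pass, it takes the 3 smallest p. It adds up to 4 members of each list by smallest p and the 5 smallest p per direction of an interaction. The 10 and 10 named for the same step in KO/FL and Lepr-Cre mice go beyond the rule, and no other gene outside it was named.

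Whether replicate letters or mice pair the libraries was checked on the correlation of their deviations from group means. A mouse gave both cell types, so mice pair those libraries by design (r = 0.0705 to 0.178). Letters were taken to pair 2 groups where all 3 correlations passed 0.1, which held for PreCFU-E of Lepr-Cre and KO/FL mice (0.107 to 0.153) and CFU-E of KO/FL and FL/FL mice (0.126 to 0.164). Libraries of the same mouse also fell below 0.1, so a correlation under it does not exclude a pairing. The B mice are female and the A and C mice male in each genotype, and what else the letters stand for is not given in the sources used here.

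Alternatives were DESeq2 size factors in edgeR, no filter on low counts, DESeq2 1.42.0, the letter or mouse as a block, limma on log2 of RPKM plus 1 and plus 0.1, sex as a covariate, the 18 or the 6 libraries of the genotype, and each library or mouse left out in turn. For lists they were an inter-gene correlation estimated from the data, fry, a block and DESeq2 size factors. A fit without CFU-E of Lepr-Cre B alone was added after seeing the data. Where a group kept 2 libraries, the pooled dispersion of the fit was used.

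The steps were tested on simulated counts drawn from the means and totals of these libraries, with 200 changed genes. In the simulated comparison of PreCFU-E of Lepr-Cre and FL/FL mice edgeR recovered 74% of the genes changed 2-fold and 97% of those changed 4-fold, with 14 unchanged genes called, of 10145 run. For CFU-E against PreCFU-E of FL/FL mice it recovered 80% of the genes changed 2-fold and 95% of those changed 4-fold, with 11 unchanged genes called, of 10479 run. For the interaction of Lepr-Cre against FL/FL it recovered 54% of the genes changed 2-fold and 91% of those changed 4-fold, with 9 unchanged genes called, of 10514 run. Unchanged genes made up 7.57%, 5.91% and 5.84% of the simulated edgeR calls, in that order. Among DESeq2 calls they made up 11.6%, 10.5% and 13.3%. Camera called the 1 changed list and 0 unchanged lists in each simulated comparison. Simulated genes were drawn independently, so this does not test list calls where genes are correlated. RPKM served only as an alternative, and no library was left out of the comparisons.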

Results

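RNA was sequenced from PreCFU-E and CFU-E, successive erythroid progenitors of the mouse, sorted from c-Kit-enriched cells and taken as whole cells. The mice carried Scf alleles of 3 genotypes: FL/FL, with floxed copies alone, KO/FL, with a null copy over a floxed copy, and KO/FL;Lepr-Cre, with Cre driven from the leptin receptor locus of stromal cells, called Lepr-Cre mice from here on. There were 3 mice per genotype, with replicate letters A, B and C, and each of the 9 mice gave a library of both cell types, 18 in all. In PreCFU-E the total counts of replicates A, B and C were 9389122, 6733640 and 7046099 in FL/FL, 3541066, 7197389 and 6535737 in KO/FL and 7281009, 9325063 and 7788825 in Lepr-Cre mice. In CFU-E they were 5460920, 8601983 and 8600071 in FL/FL, 8911102, 8815945 and 7101809 in KO/FL and 8728954, 6804445 and 6915083 in Lepr-Cre mice. Values after ± are SD over 3 libraries, log2 fold changes stand in parentheses after gene names, and groups at 0 counts are given against a floor of 3 counts over the group. Intervals and floors cover counting error only.

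The targeted gene, Kitl, encodes the ligand of KIT and is also called Scf (ENSMUSG00000019966.18, chromosome 10, 100015630 to 100100416, plus strand, GRCm38). Kitl had 0 counts in 16 of the 18 libraries and 1 count in PreCFU-E of KO/FL C and in CFU-E of KO/FL A, so the counts of these progenitors do not check the genotype of the stroma. A floor of 3 counts was between 0.320 and 0.847 CPM (counts scaled to the library total) per library. Y-linked genes had 0 to 3 counts in the 6 libraries of the B mice, labelled female, and 981 to 2718 in the 12 libraries of the A and C mice, labelled male. Kit, the receptor gene (ENSMUSG00000005672.12, chromosome 5, 75574916 to 75656722, plus strand), was read at 211 to 848 CPM, within cells that had been enriched for KIT protein.

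The first principal component of log2 CPM, with 30.8% of the variance, separated PreCFU-E from CFU-E, and the second, with 11.1%, placed the CFU-E libraries of Lepr-Cre mice below those of the other genotypes. CFU-E of Lepr-Cre B lay at -81.0 on the second component, against -13.6 for A and -12.9 for C. That library also had the fewest genes detected, 10782, and 43 of the 1223 genes of 3 to 10 CPM in CFU-E had 0 counts in it, against 0 to 6 in the other CFU-E libraries.

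**Figure D1:**
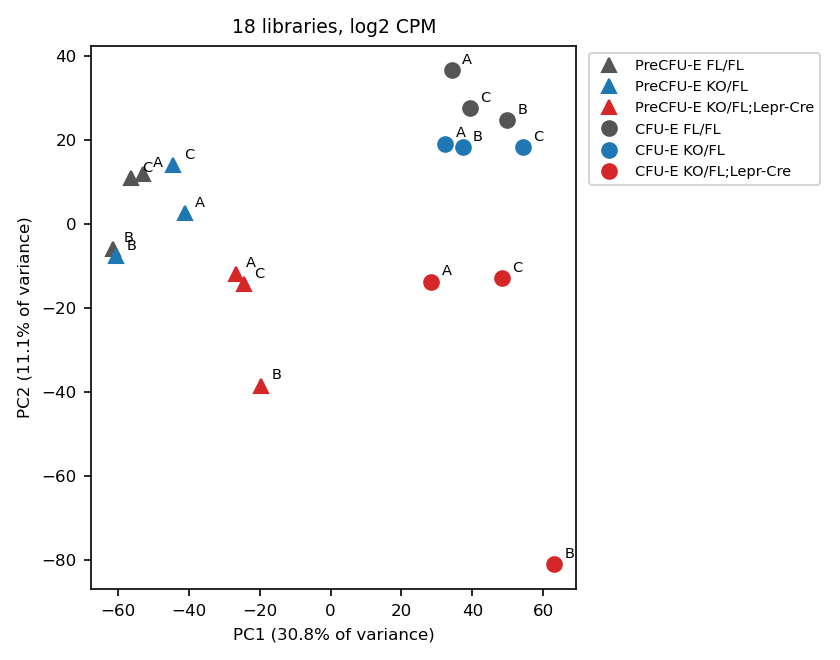
Scores of the 18 libraries on the first (x axis) and second (y axis) principal components of log2 CPM, with triangles for PreCFU-E, circles for CFU-E, a colour per genotype and letters for replicates. Cell types separate along the first component, and CFU-E of Lepr-Cre B lies at -81.0 on the second.

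PreCFU-E of Lepr-Cre mice were compared with those of FL/FL mice, a contrast that joins the null Scf copy to the added Cre. Kit itself and genes that KIT switches on through ERK were lower: Dusp6, Spry4 and Spred1, which restrain the kinase cascade, Etv5 and Egr1, transcription factors, and Ccnd1, a cyclin. Genes induced by erythropoietin through STAT5 were higher, among them Cish and Osm, together with Podxl, a surface sialomucin, and Fam132b, which codes for erythroferrone. Sptb and Add2 of the red cell membrane skeleton and Cpox of haem synthesis rose, as did Mthfd2 of the amino acid stress response. Gata2, a transcription factor gene, and Mn1 fell. edgeR called 632 of 10309 genes, 298 higher and 334 lower, of which 87 and 126 changed more than 2-fold. The share of higher genes was 47.2%, but 39.7% on log2(RPKM + 1) and 38.0% on log2(RPKM + 0.1). With all 18 libraries there were 327 higher and 265 lower, so the larger side depended on the fit. With the replicate letter as a block edgeR called 1586, 856 higher and 730 lower, while limma on either RPKM scale called fewer than 632. The count was 371 without Lepr-Cre B, 387 without Lepr-Cre C, 416 without FL/FL B and 386 without FL/FL C. In 25.2% of tested genes the 3 libraries of a group lay wholly above the 3 others, against 10% by chance. Kit averaged 437 ± 54.9 against 808 ± 62.0 CPM (log2 fold change -0.88, SE 0.12, adjusted p = 4.58e-05, n = 3 per group). Podxl (ENSMUSG00000025608.9, chromosome 6, 31519488 to 31563981, minus strand) averaged 314 ± 63.6 against 4.49 ± 3.04 CPM (log2 fold change 6.18, SE 0.77, adjusted p = 0.00763). Other large rises among separated genes of at least 5 CPM on average were those of Fam124a (6.20), Cish (4.35), St3gal6 (3.82), Rgcc (3.61), Cpd (3.56), Fam132b (3.19) and Sec14l2 (3.03). Dusp6 (ENSMUSG00000019960.8, chromosome 10, 99263231 to 99267489, plus strand) had 302 counts in the 3 FL/FL libraries and 0 in the 3 Lepr-Cre libraries, at least 102-fold lower, and Ccnd1 had 249 against 0, at least 84.2-fold lower. Spry4 (-4.94), Egr1 (-4.27), Etv5 (-3.98), Scin (-3.92), Tceal3 (-3.54) and Mn1 (-3.07) followed among the falls. Without Lepr-Cre A, Spry4 had 1 count against 588, a ratio of 415, counting interval 74.2 to 16416.

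Among 13 erythropoietin and STAT5 targets 8 rose and 0 fell (8 and 0 adjusted over the list alone), with Pim1 (1.60) and Osm (2.18) and a median of 1.82 (adjusted p = 9.02e-14 by camera, adjusted p = 0.00773 with an estimated correlation). Among 19 KIT and ERK targets 0 rose and 8 fell (0 and 9 adjusted over the list alone), with Spred1 (-1.47) and a median of -1.08 (adjusted p = 5.59e-13 by camera, adjusted p = 0.0380 with an estimated correlation). Among 22 red cell membrane genes 9 rose and 0 fell (10 and 0 adjusted over the list alone), with Add2 (0.88), Rhag (1.10) and Cldn13 (1.47) and a median of 0.29 (adjusted p = 0.0356 with an estimated correlation). Sptb (ENSMUSG00000021061.15, chromosome 12, 76580488 to 76710547, minus strand) averaged 412 ± 30.4 against 74.3 ± 11.7 CPM (log2 fold change 2.47, SE 0.14, adjusted p = 4.34e-11). Among 28 mitosis genes 8 rose and 0 fell (12 and 1 adjusted over the list alone), with Cdc20 (0.67) and Kif23 (0.63) and a median of 0.27 (adjusted p = 0.0380 with an estimated correlation).

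For the following lists the call by camera was lost with an estimated correlation. Among 28 S-phase genes 6 rose and 0 fell (8 and 0 adjusted over the list alone), with Rrm2 (1.04) and Ccne1 (1.03) and a median of 0.25 (adjusted p = 0.0553 with an estimated correlation). Each adjusted p after a median or list is given with an estimated correlation. Among 15 haem synthesis genes 4 rose and 0 fell (9 and 1 adjusted over the list alone), with Cpox (1.05), Abcb6 (0.92) and Abcb10 (0.75) and a median of 0.55 (adjusted p = 0.0553). Among 20 stem and progenitor genes 0 rose and 5 fell (0 and 5 adjusted over the list alone), with Gata2 (-1.70), Angpt1 (-1.49) and Sox4 (-1.10) and a median of -0.62 (adjusted p = 0.0634). Among 21 amino acid and unfolded protein stress genes 4 rose and 0 fell (4 and 0 adjusted over the list alone), with Atf4 (0.73) and a median of 0.29 (adjusted p = 0.166). Mthfd2 (ENSMUSG00000005667.8, chromosome 6, 83305691 to 83325908, minus strand), a member, averaged 90.7 ± 7.91 against 36.7 ± 4.30 CPM (log2 fold change 1.31, SE 0.19, adjusted p = 6.93e-05). Among 18 late erythroblast genes 3 rose and 0 fell (5 and 0 adjusted over the list alone), with a median of 0.25 (adjusted p = 0.201). Among 31 replication histones 3 rose and 0 fell (4 and 0 adjusted over the list alone), with a median of 0.25 (adjusted p = 0.361). Among 10 heat shock genes 2 rose and 0 fell (3 and 0 adjusted over the list alone), with a median of 0.33 (adjusted p = 0.166). Among 26 ribosome biogenesis genes 2 rose and 1 fell (3 and 1 adjusted over the list alone), with Noc4l (0.64) and a median of 0.11 (adjusted p = 0.355). Among 4 macrophage genes 0 rose and 1 fell (0 and 1 adjusted over the list alone), with a median of -0.57 (adjusted p = 0.0731). The macrophage gene that fell was Apoe (ENSMUSG00000002985.16, chromosome 7, 19696109 to 19699188, minus strand), an apolipoprotein gene, which averaged 94.0 ± 14.7 against 359.8 ± 50.9 CPM (log2 fold change -1.93, SE 0.21, adjusted p = 0.000205). Among 8 megakaryocyte genes 0 rose and 1 fell (0 and 2 adjusted over the list alone), with a median of -0.51 (adjusted p = 0.0797). Among 43 respiratory chain genes 0 rose and 0 fell (0 and 0 adjusted over the list alone), with a median of 0.12 (adjusted p = 0.698).

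Some lists not past the test by camera still held changed genes. Iron handling genes had 3 members higher and 1 lower of 13 (4 and 1 adjusted over the list alone), the transferrin receptor gene Tfrc (0.69) among the rises. Erythroid transcription factors went both ways, 3 higher and 2 lower of 16 (3 and 3 adjusted over the list alone), with Myb averaging 943 ± 65.1 against 2059 ± 141 CPM (log2 fold change -1.12, SE 0.11, adjusted p = 1.19e-06) and Sox6 (1.69) and Nfe2 (-0.84). The list's median was 0.03 while its mean and its test pointed down. Glycolysis genes had 2 higher and 1 lower of 21 (2 and 1 adjusted over the list alone), Pfkm (0.56) among them, and cholesterol synthesis genes 1 higher and 0 lower of 22 (1 and 0 adjusted over the list alone). Of 8 BCL2 family and 4 endothelial genes, Bcl2 (-1.24) and Plvap (-1.21) fell and 0 rose, also when adjusted over the list alone. Bcl2 did not pass without Lepr-Cre B (adjusted p = 0.0597), nor Plvap without FL/FL A (0.0562). Ribosomal protein genes had 0 higher and 1 lower of 74 (0 and 0 adjusted over the list alone). Interferon response genes had 0 higher and 0 lower of 22 (0 and 0 adjusted over the list alone), and p53 targets 0 and 0 of 16 (0 and 0 adjusted over the list alone). The medians of p53 targets and the BCL2 family differed in sign from their means or tests.

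Lepr-Cre and KO/FL mice both carry a null Scf copy, and their PreCFU-E were compared to ask what the added Cre changed. Kit, Etv5, Dusp6, Spred1 and Ccnd1 of the KIT and ERK pathway were lower, and Fam132b, Rgcc, a cell cycle regulator, and Cacna1c, a calcium channel gene, were higher. Sptb, Add2 and Cpox rose, and Gata2, Mn1 and Angpt1, an angiopoietin gene, fell. edgeR called 225 of 10309 genes, 105 higher and 120 lower, and 840 with the replicate letter as a block. There were 455 higher and 385 lower with the block and 105 higher and 83 lower with all 18 libraries. Without the block higher genes made up 46.7%, but 54.2% on log2(RPKM + 1) and 45.3% on log2(RPKM + 0.1). The count was 122 without Lepr-Cre B and 92 without KO/FL B, and 18.6% of genes had separated groups, against 10% by chance. Kit averaged 437 ± 54.9 against 714 ± 96.4 CPM (log2 fold change -0.71, SE 0.12, adjusted p = 0.00129, n = 3 per group). Among separated genes of at least 5 CPM on average, the largest rises were those of Podxl (4.16), Cpd (3.32), Fam132b (3.03), Cacna1c (2.80), Rgcc (2.68), Fam124a (2.67), Cdcp1 (2.55) and St3gal6 (2.5), and the largest falls those of Spry4 (-3.64), Etv5 (-3.27), Egr1 (-3.22), Scin (-2.69), Mn1 (-2.50), Amigo2 (-2.14), Atp4a (-2.04) and Gnaq (-2.03). Below that level, Dusp6 had 164 counts in KO/FL and 0 in Lepr-Cre mice, at least 74.5-fold lower, and Ccnd1 48 against 0, at least 21.8-fold lower. Podxl did not pass without KO/FL B (adjusted p = 0.139), KO/FL C (0.127), Lepr-Cre A (0.111), Lepr-Cre B (0.143) or Lepr-Cre C (0.10), and Cpd did not pass without KO/FL B (0.0664), KO/FL C (0.102) or Lepr-Cre B (0.0605). Fam124a did not pass without KO/FL B (adjusted p = 0.0662) or Lepr-Cre B (0.0512), and Cdcp1 did not pass without KO/FL A (0.129), KO/FL B (0.143), KO/FL C (0.102), Lepr-Cre B (0.261) or Lepr-Cre C (0.104). St3gal6 did not pass without KO/FL A (adjusted p = 0.105), KO/FL B (0.203), KO/FL C (0.176), Lepr-Cre B (0.115) or Lepr-Cre C (0.0839), and Spry4 did not pass without KO/FL A (0.0965), KO/FL B (0.132), KO/FL C (0.102) or Lepr-Cre C (0.0553). Egr1 did not pass without KO/FL B (adjusted p = 0.0563), Lepr-Cre A (0.0693), Lepr-Cre B (0.155) or Lepr-Cre C (0.110), and Atp4a did not pass without KO/FL B (0.208), Lepr-Cre B (0.127) or Lepr-Cre C (0.0667). Without Lepr-Cre A, Spry4 had 1 count against 170, a ratio of 161, counting interval 28.6 to 6408.

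Among 13 erythropoietin and STAT5 targets 5 rose and 0 fell (8 and 0 adjusted over the list alone), with Fam132b (3.03) and a median of 0.76 (adjusted p = 2.30e-11 by camera, adjusted p = 0.0153 with an estimated correlation). Each adjusted p after a median or list is given with an estimated correlation. Among 22 red cell membrane genes 5 rose and 0 fell (6 and 0 adjusted over the list alone), with Add2 (0.81) and Rhag (0.78) and a median of 0.24 (adjusted p = 0.0488). Sptb averaged 412 ± 30.4 against 123 ± 21.5 CPM (log2 fold change 1.75, SE 0.13, adjusted p = 3.86e-08). The remaining calls by camera were lost with an estimated correlation. Among 19 KIT and ERK targets 0 rose and 7 fell (0 and 8 adjusted over the list alone), with Spred1 (-1.19) and a median of -0.61 (adjusted p = 0.0572). Among 20 stem and progenitor genes 0 rose and 3 fell (0 and 7 adjusted over the list alone), with Gata2 (-1.22) and Angpt1 (-1.51) and a median of -0.77 (adjusted p = 0.0530). Among 15 haem synthesis genes 3 rose and 0 fell (7 and 0 adjusted over the list alone), with Cpox (0.82) and a median of 0.39 (adjusted p = 0.0530). Among 28 S-phase genes 2 rose and 0 fell (8 and 0 adjusted over the list alone), with Rrm2 (0.79) and Ccne1 (0.73) and a median of 0.21 (adjusted p = 0.0617). Among 21 amino acid and unfolded protein stress genes 3 rose and 0 fell (3 and 0 adjusted over the list alone), with Mthfd2 (1.04) and Atf4 (0.64) and a median of 0.23 (adjusted p = 0.220). Among 4 macrophage genes 0 rose and 1 fell (0 and 1 adjusted over the list alone), with Apoe (-1.75) and a median of -0.41 (adjusted p = 0.0632). Of 28 mitosis, 18 late erythroblast, 13 iron handling, 4 endothelial and 8 megakaryocyte genes, 1, 2, 1, 0 and 0 rose and 0, 0, 0, 1 and 0 fell, respectively, and 5, 3, 2, 0 and 0 rose and 0, 1, 0, 1 and 0 fell adjusted over the list alone. Their medians were 0.17, 0.33, 0.19, -0.78 and -0.32 (adjusted p = 0.0632, 0.150, 0.122, 0.223 and 0.150). Of 31 replication histone, 26 ribosome biogenesis and 10 heat shock genes, 0, 0 and 0 rose and 0, 0 and 0 fell, respectively, and 2, 0 and 2 rose and 0, 0 and 0 fell adjusted over the list alone. Their medians were 0.22, 0.11 and 0.31 (adjusted p = 0.310, 0.245 and 0.156). Myb averaged 943 ± 65.1 against 1753 ± 205 CPM (log2 fold change -0.89, SE 0.11, adjusted p = 6.19e-05), in a transcription factor list not past the test.

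KO/FL and FL/FL mice differ by the null copy of Scf in every cell. No gene of their PreCFU-E passed with edgeR without a block. The genes nearest to the threshold included Sptb and Pim1, which were higher in Lepr-Cre mice, and Gata2, which was lower there. At an unadjusted p under 0.05 there were 350 genes of 10309, and 9.03% had separated groups, against 10% by chance. DESeq2 called 5 genes, edgeR without a filter on low counts 9, and edgeR 1 without FL/FL B and 1 without FL/FL C. With the replicate letter as a block edgeR called 9, Sptb, Ptger3 and Pim1 among them. The 3 smallest p-values in each direction belonged to Sptb (0.72), Ptger3 (1.09) and Pim1 (0.85) and to Zbtb16 (-0.85), Dedd2 (-0.63) and Gata2 (-0.48), none past the threshold without the block (adjusted p = 0.190 or more). Kit averaged 714 ± 96.4 against 808 ± 62.0 CPM (log2 fold change -0.17, SE 0.12, adjusted p = 1.0). Camera called 6 lists without a called gene in any of them, and none of these calls held with an estimated correlation. The medians were -0.53 for the KIT and ERK list (adjusted p = 0.404 with an estimated correlation), 0.68 for erythropoietin targets (0.231), 0.09 for mitosis (0.404), 0.07 for red cell membrane genes (0.606), -0.10 for erythroid transcription factors (0.742) and 0.06 for the respiratory chain (0.993). Adjusted over the list alone, 1 erythropoietin target and 1 red cell membrane gene rose and 1 stem and progenitor gene fell.

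Lepr-Cre and FL/FL mice were also compared in CFU-E, the later progenitor, where the null copy and Cre again go together. Kit, Spry4, Spred1, Spred2 and Etv5 were lower and Podxl, Cish and Fam132b higher, along with Plek2, a pleckstrin gene, and C2cd4a, a nuclear factor gene of little studied function. Against the direction of its list, Ccnd2, a cyclin gene, rose. Mthfd2, Shmt2 and Psat1, enzymes of serine and folate metabolism, rose, and Hhex, a homeobox gene, and Gp5, a platelet glycoprotein gene, fell. edgeR called 492 of 10192 genes, 212 higher and 280 lower, and 70 and 109 changed more than 2-fold. With the replicate letter as a block it called 933, 439 higher and 494 lower, while limma on either RPKM scale called fewer than 492. The share of higher genes was 43.1%, but 33.0% on log2(RPKM + 0.1). The count was 226 without FL/FL A and 246 without FL/FL B, and 22.2% of genes had separated groups, against 10% by chance. Kit averaged 247 ± 46.9 against 413 ± 55.3 CPM (log2 fold change -0.73, SE 0.14, adjusted p = 0.00539, n = 3 per group). C2cd4a had 0 counts in FL/FL and 322 in Lepr-Cre mice, at least 110.4-fold higher. Cish (ENSMUSG00000032578.7, chromosome 9, 107296026 to 107302784, plus strand) averaged 12.4 ± 1.66 against 0.279 ± 0.386 CPM (log2 fold change 5.64, SE 0.86, adjusted p = 0.000369). The other large rises at 5 CPM or more were those of Podxl (6.87), Fam124a (6.28), Plek2 (5.08), Cdcp1 (4.36), Fam132b (3.88) and B3gnt7 (3.48). Spry4 (ENSMUSG00000024427.7, chromosome 18, 38586247 to 38601415, minus strand) averaged 0.352 ± 0.310 against 11.6 ± 0.850 CPM (log2 fold change -4.92, SE 0.65, adjusted p = 8.52e-05). Amigo2 (-4.21), Pcdh7 (-3.16), Fhdc1 (-3.14), Etv5 (-3.00), Hhex (-2.68), Gnaq (-2.66) and Gp5 (-2.61) were the other large falls. Fam124a did not pass without FL/FL A (adjusted p = 0.0809) or FL/FL C (0.0780). Cdcp1 was at least 45.4-fold higher without FL/FL B, with 0 counts left in a group.

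Camera called 12 lists, and none of these calls held with an estimated correlation. Among 11 erythropoietin and STAT5 targets 6 rose and 0 fell (7 and 0 adjusted over the list alone), with Pim1 (1.52) and Osm (2.11) and a median of 1.52 (adjusted p = 0.0531 with an estimated correlation). Each adjusted p after a median or list is given with an estimated correlation. Among 18 KIT and ERK targets 1 rose and 6 fell (2 and 6 adjusted over the list alone), with Spred1 (-1.37) and Spred2 (-1.28) and a median of -0.76 (adjusted p = 0.418). Ccnd2, which rose in that list of falling genes, averaged 259 ± 33.6 against 123 ± 13.1 CPM (log2 fold change 1.09, SE 0.17, adjusted p = 0.00103). Among 20 amino acid and unfolded protein stress genes 5 rose and 0 fell (6 and 0 adjusted over the list alone), with Mthfd2 (1.41), Shmt2 (0.71) and Psat1 (0.79) and a median of 0.34 (adjusted p = 0.152). Among 26 ribosome biogenesis genes 4 rose and 0 fell (11 and 0 adjusted over the list alone), with Srm (0.63) and a median of 0.23 (adjusted p = 0.176). Among 11 heat shock genes 2 rose and 0 fell (3 and 0 adjusted over the list alone), with Hspd1 (0.59) and a median of 0.39 (adjusted p = 0.305). Among 28 S-phase genes 2 rose and 0 fell (3 and 0 adjusted over the list alone), with Rrm2 (0.56) and a median of 0.17 (adjusted p = 0.446). Among 16 haem synthesis genes 1 rose and 0 fell (2 and 0 adjusted over the list alone), with Cpox (0.52) and a median of 0.20 (adjusted p = 0.446). Among 3 endothelial genes 0 rose and 1 fell (0 and 1 adjusted over the list alone), with Plvap (-1.86) and a median of -0.98 (adjusted p = 0.305). Of 28 mitosis, 31 replication histone, 4 globin and 22 glycolysis genes, 2, 1, 1 and 0 rose and 0, 0, 0 and 0 fell, respectively, and 5, 4, 2 and 0 rose and 1, 0, 0 and 0 fell adjusted over the list alone. Their medians were 0.14, 0.23, 1.11 and 0.32 (adjusted p = 0.629, 0.668, 0.446 and 0.418). Among lists not past the test, Myb averaged 438 ± 119 against 847 ± 52.9 CPM (log2 fold change -0.94, SE 0.15, adjusted p = 0.000825) and Ctse, a cathepsin gene of late erythroblasts, fell (-0.76). Dmtn was the only red cell membrane gene of 24 to rise (0.82, 1 and 0 adjusted over the list alone), in a list with a median of 0.01. Stem cell, late erythroblast, ribosomal protein and p53 lists had medians and means or tests of different sign, all short of the threshold. Dmtn did not pass without FL/FL A (adjusted p = 0.0705), FL/FL C (0.0778), Lepr-Cre B (0.0982) or Lepr-Cre C (0.0841).

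**Figure D2:**
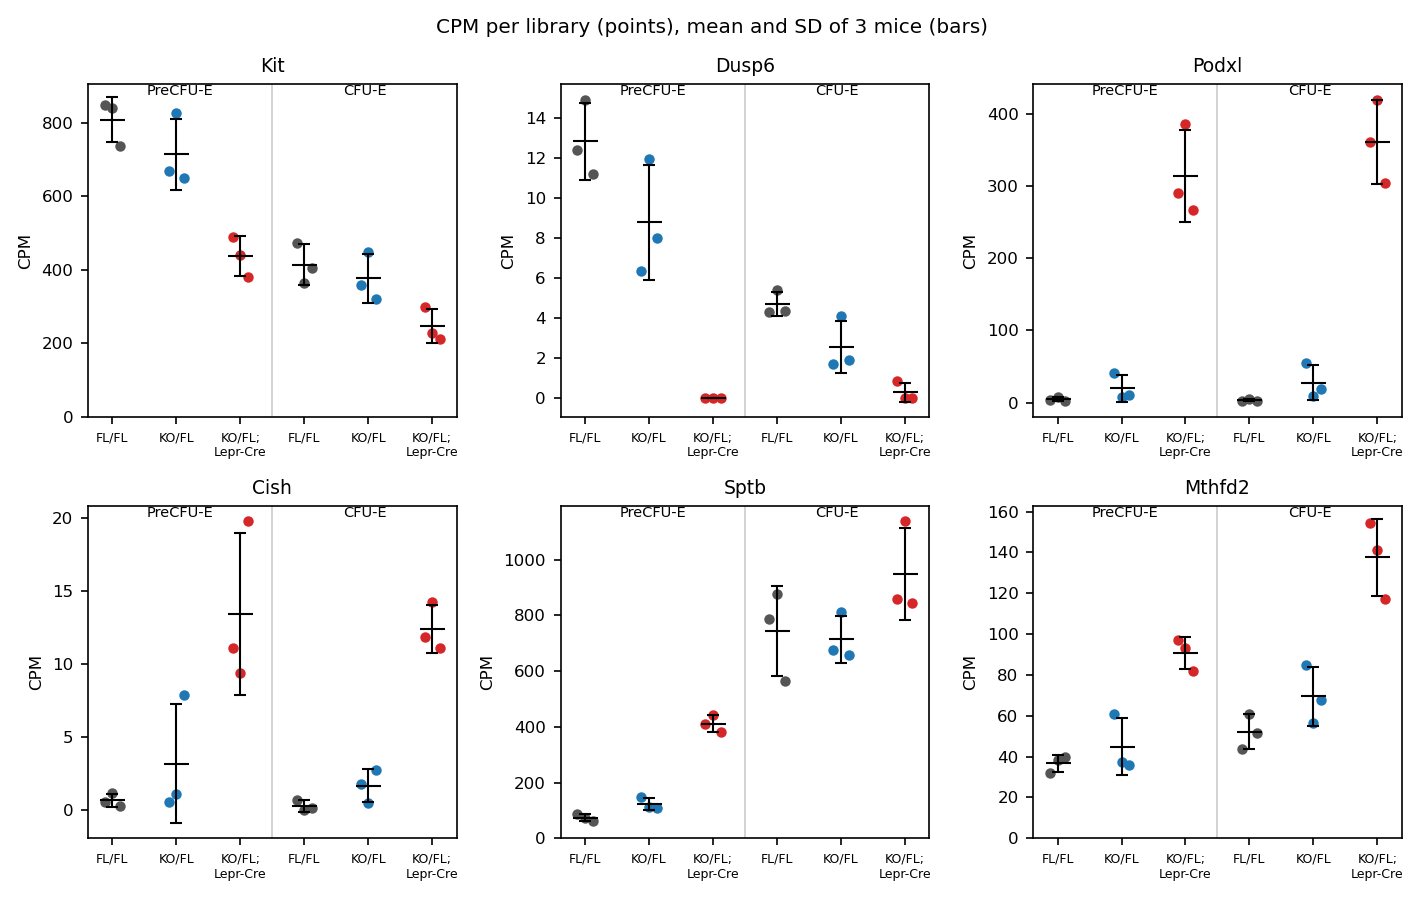
CPM of Kit, Dusp6, Podxl, Cish, Sptb and Mthfd2 in each of the 18 libraries (y axis), by cell type and genotype (x axis), with bars for the mean and SD of 3 libraries. Kit was lower and Podxl, Cish and Mthfd2 were higher in Lepr-Cre mice than in FL/FL mice in both cell types, Kit at 437 against 808 CPM in PreCFU-E.

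CFU-E of Lepr-Cre and KO/FL mice were compared to ask what the added Cre changed at the later step. Spry4 and Spred1 of the ERK feedback group and Kit fell, and Cish, Osm and Fam132b, erythropoietin targets, rose. Fabp5, a fatty acid binding protein gene, and Tspan14, a tetraspanin gene, rose, and Pcdh7, a protocadherin gene, fell. edgeR called 103 of 10192 genes, 30 higher and 73 lower. The count was 52 without Lepr-Cre B, 19 without KO/FL B and 54 without KO/FL C, and 17.2% of genes had separated groups, against 10% by chance. The share of higher genes was 29.1%, but 51.7% on log2(RPKM + 1) and 45% on log2(RPKM + 0.1). Kit averaged 247 ± 46.9 against 377 ± 65.9 CPM (log2 fold change -0.60, SE 0.14, adjusted p = 0.0486, n = 3 per group). Of the separated genes with at least 5 CPM on average, C2cd4a (5.64), Cish (2.92), Fabp5 (2.79), Fam132b (2.15), Cpd (2.09), Tspan14 (2.07), Osm (1.81) and Prkcq (1.80) had the largest rises. Amigo2 (-3.47), Pcdh7 (-2.57), Gnaq (-2.15), Hhex (-2.14), Gp5 (-2.10), Rasgef1c (-1.94), Ifngr2 (-1.86) and Trim2 (-1.84) had the largest falls of such genes. Kit did not pass without KO/FL A (adjusted p = 0.0825), KO/FL B (0.285), Lepr-Cre B (0.178) or Lepr-Cre C (0.145), and Cish did not pass without KO/FL A (0.0986), KO/FL B (0.216), Lepr-Cre A (0.0970), Lepr-Cre B (0.127) or Lepr-Cre C (0.0920). Fam132b did not pass without KO/FL B (adjusted p = 0.157), KO/FL C (0.0786) or Lepr-Cre B (0.105), and Cpd did not pass without KO/FL B (0.188), KO/FL C (0.0725) or Lepr-Cre B (0.0865). Osm did not pass without KO/FL B (adjusted p = 0.0823), KO/FL C (0.0674) or Lepr-Cre C (0.0534), and Prkcq did not pass without KO/FL A (0.0593), KO/FL C (0.0725) or Lepr-Cre B (0.0563). Amigo2 did not pass without KO/FL A (adjusted p = 0.0787), KO/FL B (0.184), KO/FL C (0.116), Lepr-Cre A (0.0555) or Lepr-Cre C (0.121), and Gnaq did not pass without KO/FL B (0.184), KO/FL C (0.128) or Lepr-Cre C (0.157). Hhex did not pass without KO/FL B (adjusted p = 0.0823), and Gp5 did not pass without KO/FL B (0.0881), Lepr-Cre A (0.0629) or Lepr-Cre C (0.0616). Rasgef1c did not pass without KO/FL B (adjusted p = 0.184), Lepr-Cre A (0.0969) or Lepr-Cre C (0.0842), and Ifngr2 did not pass without KO/FL A (0.0657), KO/FL B (0.126), KO/FL C (0.0756) or Lepr-Cre B (0.0841). Trim2 did not pass without KO/FL B (adjusted p = 0.392), KO/FL C (0.0614), Lepr-Cre A (0.0616), Lepr-Cre B (0.138) or Lepr-Cre C (0.117). C2cd4a was at least 77.3-fold higher without KO/FL A, with 0 counts left in a group.

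Among 11 erythropoietin and STAT5 targets 4 rose and 0 fell (6 and 0 adjusted over the list alone), with Pim1 (1.03) and a median of 1.03 (adjusted p = 1.24e-08 by camera, adjusted p = 0.0472 with an estimated correlation). Each adjusted p after a median or list is given with an estimated correlation. The other 8 calls by camera were lost with an estimated correlation. Among 20 amino acid and unfolded protein stress genes 2 rose and 0 fell (7 and 0 adjusted over the list alone), with Mthfd2 (0.99) and Shmt2 (0.52) and a median of 0.34 (adjusted p = 0.138). Of 26 ribosome biogenesis, 11 heat shock, 31 replication histone and 4 globin genes, 0, 0, 0 and 0 rose and 0, 0, 0 and 0 fell, respectively, and 0, 0, 0 and 2 rose and 0, 0, 0 and 0 fell adjusted over the list alone. Their medians were 0.20, 0.36, 0.20 and 1.21 (adjusted p = 0.253, 0.278, 0.697 and 0.278). Of 16 haem synthesis, 28 S-phase and 22 glycolysis genes, 0, 0 and 0 rose and 0, 0 and 0 fell, respectively, and 2, 0 and 0 rose and 0, 0 and 0 fell adjusted over the list alone. Their medians were 0.20, 0.10 and 0.19 (adjusted p = 0.454, 0.668 and 0.668). Among 18 KIT and ERK targets 1 rose and 3 fell (3 and 5 adjusted over the list alone), with Spry4 (-3.99), Spred1 (-1.18) and Spred2 (-0.88) and a median of -0.07 (adjusted p = 0.697), short of the threshold with either correlation. The member that rose was Ccnd2 (0.81). Myb averaged 438 ± 119 against 719.9 ± 80.4 CPM (log2 fold change -0.71, SE 0.15, adjusted p = 0.0227). Mthfd2 did not pass without KO/FL B (adjusted p = 0.0548), and Shmt2 did not pass without KO/FL B (0.157), KO/FL C (0.0547) or Lepr-Cre B (0.0816). Spred2 did not pass without KO/FL A (adjusted p = 0.0787), KO/FL B (0.238), KO/FL C (0.0708), Lepr-Cre A (0.0546) or Lepr-Cre B (0.111), and Pim1 did not pass without KO/FL B (0.112) or Lepr-Cre A (0.0665). Ccnd2 did not pass without KO/FL B (adjusted p = 0.199), KO/FL C (0.0708), Lepr-Cre A (0.0986), Lepr-Cre B (0.0816) or Lepr-Cre C (0.0618), and Myb did not pass without KO/FL B (0.157), Lepr-Cre B (0.0964) or Lepr-Cre C (0.0945).

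No gene differed between CFU-E of KO/FL and FL/FL mice with edgeR, either without or with the replicate letter as a block. Of 10192 genes, 210 had an unadjusted p under 0.05, and 8.14% had separated groups, against 10% by chance. DESeq2 called 1 gene, edgeR without a filter on low counts 2, and edgeR 1 without KO/FL C. The 3 smallest p-values in each direction belonged to Cacna1c (1.05), Phldb1 (1.09) and Mef2c (1.08) and to Txnip (-0.74), Mylk3 (-0.58) and St5 (-0.83), none past the threshold (adjusted p = 1.0). Kit averaged 377 ± 65.9 against 413 ± 55.3 CPM (log2 fold change -0.13, SE 0.14, adjusted p = 1.0). Camera called erythropoietin targets (median 0.30, adjusted p = 0.394 with an estimated correlation), the KIT and ERK list (-0.71, adjusted p = 0.801 with an estimated correlation) and glycolysis (0.14, adjusted p = 0.801 with an estimated correlation), and 5 lists with the block. Among erythropoietin targets 3 and 0 rose and fell adjusted over the list alone.

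**Figure D3:**
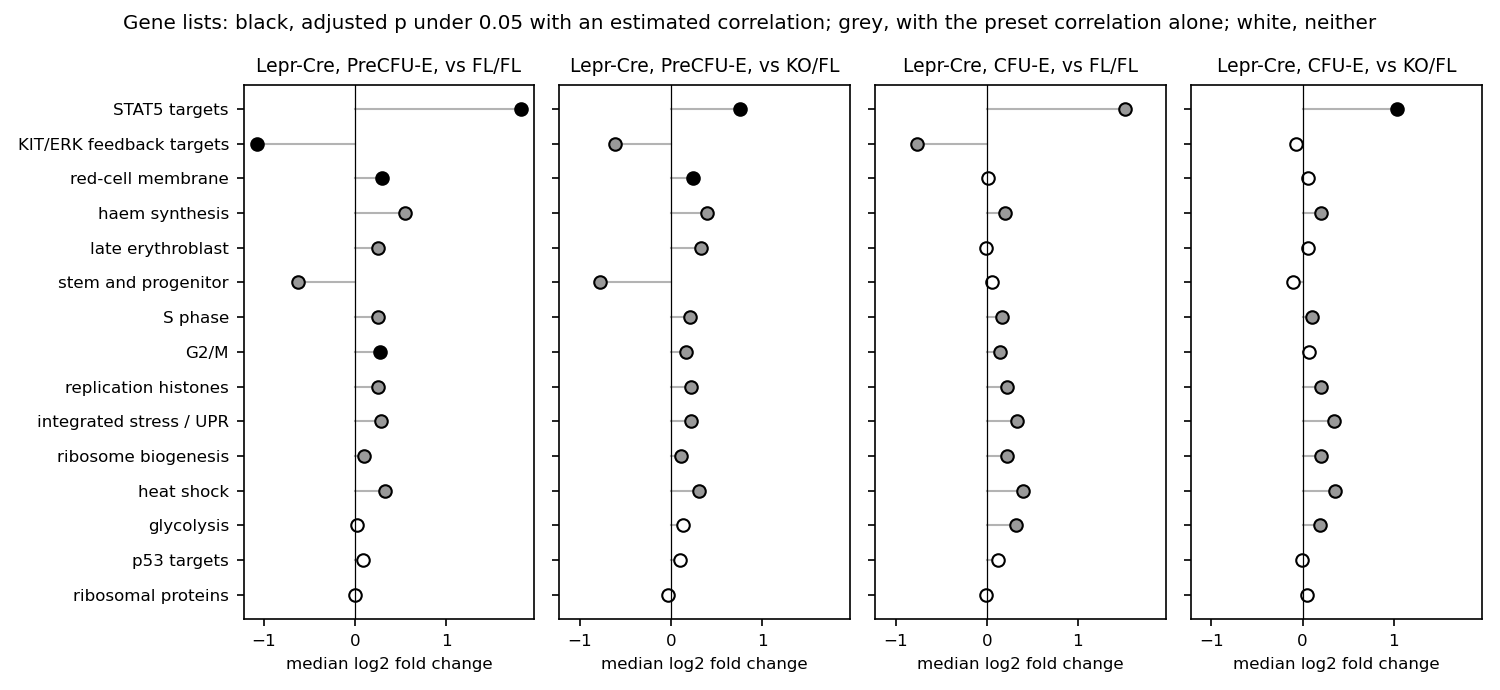
Median log2 fold change (x axis) of 15 gene lists (y axis) in the 4 comparisons of Lepr-Cre mice with FL/FL or KO/FL mice, with black points for lists past an adjusted p of 0.05 with an estimated correlation, grey for lists past it with the preset correlation alone and white for the others. Erythropoietin and STAT5 targets had medians from 0.76 to 1.82.

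CFU-E were compared with PreCFU-E within each genotype to describe the step between them. In FL/FL mice genes of the mature red cell rose: Slc4a1, the band 3 anion exchanger, Epb42 and Sptb of the membrane skeleton, Trim10, the alpha globin gene Hba-a1 and Uros and Abcb10 of haem synthesis. Genes of stem and early progenitor cells fell, such as Fli1, Meis1 and Angpt1. Coro1a, Vim, Scin, Apoe and Kit fell as well. edgeR called 1963 of 10732 genes in FL/FL mice, 965 higher and 998 lower in CFU-E, 301 and 551 of them by more than 2-fold. The share of higher genes was 49.2%, but 41.3% on log2(RPKM + 1) and 41.8% on log2(RPKM + 0.1), and the mouse as a block gave 1420 higher and 1286 lower. The count was 1293 without FL/FL A and 929 without FL/FL B, and 35.0% of genes had separated groups, against 10% by chance. Slc4a1 (ENSMUSG00000006574.15, chromosome 11, 102348824 to 102366203, minus strand) had 0 counts in PreCFU-E and 298 in CFU-E, at least 104-fold higher. Fhdc1 (6.91), Cacna1e (5.55), Scd1 (5.09), Trim2 (4.97), Sec14l2 (4.90), Rab3il1 (4.71), St3gal6 (4.45), Hba-a1 (4.15) and Trim10 (4.15) completed the 10 largest rises of separated genes of at least 5 CPM on average. Coro1a had 286 counts in PreCFU-E and 1 in CFU-E, a ratio of 273, counting interval 48.6 to 10812, and Gmfg 235 and 2, a ratio of 112, counting interval 30.7 to 931. The other large falls of such genes were those of Scin (-5.99), Spns3 (-5.97), Rab37 (-5.59), Vim (-5.50), Abcg1 (-5.36), Itgal (-5.09), St8sia6 (-5.01) and Plac8 (-4.99). Kit averaged 413 ± 55.3 against 808 ± 62.0 CPM (log2 fold change -0.97, SE 0.14, adjusted p = 1.24e-05, n = 3 per group). Fhdc1 was at least 138-fold higher without FL/FL A, with 0 counts left in a group.

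The calls of 8 lists held with an estimated correlation. Among 25 red cell membrane genes 18 rose and 0 fell (20 and 0 adjusted over the list alone), with Sptb (3.32), Epb42 (3.14) and Add2 (1.24) and a median of 1.07 (adjusted p = 0.000374 with an estimated correlation). In the rest of the paragraph, the adjusted p of a list is given with an estimated correlation. Among 21 late erythroblast genes 15 rose and 0 fell (15 and 0 adjusted over the list alone), with Ctse (1.81) and Hemgn (1.70) and a median of 1.70 (adjusted p = 0.00146). Among 16 haem synthesis genes 11 rose and 0 fell (11 and 1 adjusted over the list alone), with Abcb10 (1.65) and Uros (1.94) and a median of 0.91 (adjusted p = 0.00249). Among 28 S-phase genes 21 rose and 0 fell (24 and 0 adjusted over the list alone), with Ccne1 (1.54) and Rrm2 (1.36) and a median of 0.51 (adjusted p = 0.0113). Among 13 iron handling genes 7 rose and 1 fell (7 and 1 adjusted over the list alone), with Tfrc (1.18) and a median of 0.38 (adjusted p = 0.0210). Among 4 globins 4 rose and 0 fell (4 and 0 adjusted over the list alone), with a median of 5.97, or 5.05 with genes at 0 in a group at their bound (adjusted p = 0.0210), and Hbb-bs was at least 21.3-fold higher. Among 21 stem and progenitor genes 0 rose and 11 fell (0 and 16 adjusted over the list alone), with Fli1 (-3.28), Meis1 (-3.79) and Angpt1 (-2.20) and a median of -2.20 (adjusted p = 0.00199). Among 5 macrophage genes 0 rose and 2 fell (0 and 2 adjusted over the list alone), with a median of -0.91 (adjusted p = 0.0304), with Apoe at 22.3 ± 4.31 against 359.8 ± 50.9 CPM. The other calls were lost with an estimated correlation. Among 19 KIT and ERK targets 0 rose and 5 fell (0 and 5 adjusted over the list alone), with Myc (-0.97) and Egr1 (-3.18) and a median of -0.86 (adjusted p = 0.161). Of 28 mitosis, 31 replication histone, 22 glycolysis, 43 respiratory chain and 26 ribosome biogenesis genes, 12, 7, 2, 2 and 0 rose and 0, 0, 9, 0 and 5 fell, respectively, and 16, 10, 3, 0 and 0 rose and 0, 0, 12, 0 and 5 fell adjusted over the list alone. Their medians were 0.34, 0.43, -0.45, 0.27 and -0.20 (adjusted p = 0.0572, 0.525, 0.197, 0.706 and 0.328). Of the sort markers, which were left out of the adjustment, 2 of 6 rose and 4 fell, with Slamf1, which codes for CD150, at 4.16 CPM in PreCFU-E and 0.0785 in CFU-E.

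In KO/FL mice Slc4a1, Hba-a1, Trim10, Sec14l2 and Cacna1e rose, and Rab37, a small GTPase gene, Vim, Abcg1, a cholesterol transporter gene, and Plac8 fell. edgeR called 1510 of 10732 genes, 739 higher and 771 lower, 996 without KO/FL A, 859 without KO/FL B and 987 without KO/FL C, and 31% had separated groups, against 10% by chance. Rising genes made up 48.9%, but 40.5% on log2(RPKM + 1) and 41.2% on log2(RPKM + 0.1), and the mouse as a block gave 1103 higher and 1049 lower. Slc4a1 had 3 counts in PreCFU-E and 314 in CFU-E, a ratio of 74.7, counting interval 25.3 to 364. Among separated genes of at least 5 CPM on average, other large rises were those of Rab3il1 (5.13), Cacna1e (4.63), Fhdc1 (4.58), Hba-a1 (4.22), Trim10 (4.13), Tspan15 (3.85), Sec14l2 (3.78), Rgcc (3.42) and Slc46a3 (3.34), and Rab37 (-5.65), Atp10a (-5.41), Vim (-5.07), Abcg1 (-4.78), Lcp2 (-4.44), Spns3 (-4.29), Kctd12 (-4.20), Plac8 (-3.85), Adgrg3 (-3.83) and Pkm (-3.83) had the largest falls. Kit averaged 377 ± 65.9 against 714 ± 96.4 CPM (log2 fold change -0.92, SE 0.14, adjusted p = 2.98e-05). Kctd12 did not pass without KO/FL A (adjusted p = 0.0682), KO/FL B (0.212) or KO/FL C (0.0629), and Pkm did not pass without KO/FL A (0.118), KO/FL B (0.0807) or KO/FL C (0.140). Slc4a1 was at least 50.6-fold higher without KO/FL C, with 0 counts left in a group.

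In Lepr-Cre mice the step comprised fewer called genes. Slc4a1, Hba-a1, Trim10 and Sec14l2 rose, and Rab37, Slamf1, Vim and Zbtb16, a zinc finger gene of early progenitors, fell. edgeR called 778 of 10732 genes, 322 higher and 456 lower, 1322 with the mouse as a block and 373 without Lepr-Cre B and 362 without Lepr-Cre C, and 22.3% had separated groups, against 10% by chance. Genes higher in CFU-E made up 41.4%, but 41.2% on log2(RPKM + 1) and 36.9% on log2(RPKM + 0.1). Of separated genes of at least 5 CPM on average, the largest rises were those of Slc4a1 (3.27), Hbb-bt (2.67), Hba-a1 (2.62), Apol8 (2.47), Rab3il1 (2.42), Slc46a3 (2.36), Sh3tc2 (2.32), Trim10 (2.22), Scd1 (2.21) and Sec14l2 (2.06). Rab37 (-4.95), Slamf1 (-4.68), Plxdc2 (-3.81), Parm1 (-3.63), Rin3 (-3.51), Col1a2 (-3.47), Kdelc2 (-3.37), Vim (-3.29), Zbtb16 (-3.23) and Spns3 (-3.09) had the largest falls of such genes. Kit averaged 247 ± 46.9 against 437 ± 54.9 CPM (log2 fold change -0.82, SE 0.14, adjusted p = 0.000403). Hbb-bt did not pass without Lepr-Cre B (adjusted p = 0.176) or Lepr-Cre C (0.0702), and Apol8 did not pass without Lepr-Cre A (0.0966), Lepr-Cre B (0.187) or Lepr-Cre C (0.128). Rab3il1 did not pass without Lepr-Cre B (adjusted p = 0.0960), and Plxdc2 did not pass without Lepr-Cre A (0.493) or Lepr-Cre B (0.126). Rin3 did not pass without Lepr-Cre A (adjusted p = 0.0684) or Lepr-Cre C (0.176), and Col1a2 did not pass without Lepr-Cre A (0.0515). Kdelc2 did not pass without Lepr-Cre A (adjusted p = 0.0763) or Lepr-Cre B (0.0582), and Vim did not pass without Lepr-Cre C (0.151). Spns3 did not pass without Lepr-Cre A (adjusted p = 0.0522). Rab37 was at least 46.6-fold lower without Lepr-Cre A, Slamf1 was at least 47.2-fold lower without Lepr-Cre C and Plxdc2 was at least 58.1-fold lower without Lepr-Cre C, each with 0 counts left in a group. Plxdc2 had a log2 fold change of -1.97 without Lepr-Cre A and Vim one of -5.76 without Lepr-Cre A.

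Groups of the step in KO/FL and Lepr-Cre mice, in that order, were as follows. Among 25 red cell membrane genes 18 and 17 rose and 0 and 1 fell (adjusted over the list alone 20 and 18 rose and 0 and 1 fell), with Epb42 at 3.07 and 2.03 and medians of 0.84 and 0.53 (adjusted p = 0.000514 and 0.00198 with an estimated correlation). In the rest of the paragraph, the adjusted p of a list is given with an estimated correlation. Among 21 late erythroblast genes 15 and 13 rose and 0 and 0 fell (adjusted over the list alone 16 and 15 rose and 0 and 0 fell), with Ctse at 1.73 and 0.99 and medians of 1.38 and 0.99 (adjusted p = 0.000608 and 0.00198). Among 16 haem synthesis genes 11 and 11 rose and 0 and 0 fell (adjusted over the list alone 11 and 11 rose and 0 and 0 fell), with medians of 0.84 and 0.63 (adjusted p = 0.000687 and 0.00209). Among 28 S-phase genes 21 and 12 rose and 0 and 0 fell (adjusted over the list alone 23 and 21 rose and 0 and 0 fell), with Ccne1 at 1.36 and 0.94 and medians of 0.48 and 0.36 (adjusted p = 0.00543 and 0.00530). Among 13 iron handling genes 6 and 3 rose and 0 and 0 fell (adjusted over the list alone 7 and 4 rose and 0 and 0 fell), with medians of 0.27 and 0.13 (adjusted p = 0.00816 and 0.0330). Among 4 globins 3 and 3 rose and 0 and 0 fell (adjusted over the list alone 3 and 3 rose and 0 and 0 fell), with medians of 3.86 and 2.65 (adjusted p = 0.0353 and 0.0237). Among 21 stem and progenitor genes 0 and 0 rose and 12 and 7 fell (adjusted over the list alone 0 and 0 rose and 16 and 7 fell), with Fli1 at -3.34 and -2.03 and medians of -2.64 and -1.41 (adjusted p = 0.000608 and 0.00530), or -2.36 in KO/FL mice with genes at 0 in a group at their bound. Among 5 macrophage genes 0 and 0 rose and 1 and 1 fell (adjusted over the list alone 0 and 0 rose and 1 and 2 fell), with Apoe at -3.70 and -2.12 and medians of -1.50 and -1.28 (adjusted p = 0.0151 and 0.0310). Among 9 megakaryocyte genes 0 and 1 rose and 3 and 2 fell (adjusted over the list alone 0 and 1 rose and 4 and 5 fell), with medians of -1.12 and -0.90 (adjusted p = 0.0656 and 0.0330). Among 28 mitosis genes 8 and 3 rose and 0 and 0 fell (adjusted over the list alone 10 and 3 rose and 0 and 0 fell), with medians of 0.25 and 0.16 (adjusted p = 0.0878 and 0.139). Among 31 replication histones 5 and 2 rose and 0 and 0 fell (adjusted over the list alone 5 and 5 rose and 0 and 0 fell), with medians of 0.42 and 0.36 (adjusted p = 0.444 and 0.355). Among 43 respiratory chain genes 0 and 0 rose and 0 and 0 fell (adjusted over the list alone 0 and 0 rose and 0 and 0 fell), with medians of 0.18 and 0.13 (adjusted p = 0.740 and 0.710). Of 19 KIT and ERK genes in KO/FL mice, 0 rose and 4 fell (0 and 5 adjusted over the list alone), with a median of -0.91 (adjusted p = 0.143). Of 4 endothelial genes in Lepr-Cre mice, 0 rose and 2 fell (0 and 3 adjusted over the list alone), with a median of -1.50 (adjusted p = 0.139). In Lepr-Cre mice the KIT and ERK list had a positive median and mean and a test pointing down, with Myc (-0.79) its only member to fall.

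Whether the genotype changed the step itself was tested as an interaction between genotype and cell type. Between Lepr-Cre and FL/FL mice, Sptb rose less from PreCFU-E to CFU-E in Lepr-Cre mice, whose PreCFU-E had more of it, and Cnn3, a calponin gene, Lmna, a lamin gene, Btnl10 and Hpn, a serine protease gene, followed the same sign. Coro1a, Wdfy4, Mef2c, Abca2 and Arpc1b had the opposite sign. edgeR called 38 of 10732 genes, 15 positive and 23 negative, against 198 with the mouse as a block. The count was 21 without Lepr-Cre A, 23 without Lepr-Cre C and 13 without FL/FL B. Sptb went from 74.3 to 744 CPM in FL/FL and from 412 to 947 CPM in Lepr-Cre mice (log2 fold change -2.12, SE 0.23, adjusted p = 5.52e-05), with Cnn3 (-2.35), Lmna (-1.12), Btnl10 (-1.74) and Hpn (-1.66) behind it. The positive differences were those of Wdfy4 (2.05), Mef2c (1.86), Abca2 (1.35) and Arpc1b (1.67), and that of Coro1a rests on 1 count in CFU-E of FL/FL mice. Abca2 did not pass without FL/FL B (adjusted p = 0.0629), and Arpc1b did not pass without FL/FL B (0.0691). Kit showed no called difference (0.14, 0.10 and 0.04 in the 3 interactions).

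Red cell membrane genes had a median difference of -0.44, or -0.41 with genes at 0 in a group left out, between Lepr-Cre and FL/FL mice, with 3 of 25 past the threshold (0 and 9 adjusted over the list alone, adjusted p = 0.0102 with an estimated correlation). Each adjusted p after a median or list is given with an estimated correlation. The other lists called by camera were late erythroblast genes (-0.46, 2 of 21, adjusted p = 0.0836), globins (-3.50, or -3.57 with genes at 0 in a group left out, adjusted p = 0.226), haem synthesis (-0.13, adjusted p = 0.325), mitosis (-0.17, adjusted p = 0.325), stem and progenitor genes (0.87, adjusted p = 0.0793), the KIT and ERK list (0.76, or 0.50 with genes at 0 in a group left out, adjusted p = 0.293) and glycolysis (0.31, adjusted p = 0.408). Between Lepr-Cre and KO/FL mice edgeR called 0 genes, with 569 at an unadjusted p under 0.05, 23 by DESeq2, 61 with the mouse as a block and 1 without Lepr-Cre B, 2 without KO/FL A and 2 without KO/FL C. In 2 lists there the call held with an estimated correlation, red cell membrane genes (-0.29, adjusted p = 0.0350) and stem and progenitor genes (1.15, adjusted p = 0.0350). Late erythroblast, KIT and ERK, haem synthesis and S-phase lists did not (adjusted p = 0.0591, 0.198, 0.187 and 0.544). Between KO/FL and FL/FL mice edgeR and DESeq2 called 0 genes, with 249 at an unadjusted p under 0.05, and camera called red cell membrane genes (-0.16, adjusted p = 0.987).

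Markers of other cells were summed per library. Macrophage markers, mostly Apoe, summed to 369 ± 52.4, 327 ± 92.0 and 104 ± 15.9 CPM in PreCFU-E of FL/FL, KO/FL and Lepr-Cre mice and to 28.3 ± 3.97, 30.5 ± 3.89 and 28.2 ± 2.83 CPM in CFU-E. B cell markers, in the same order, summed to 2.90 ± 1.84, 2.84 ± 2.49 and 2.38 ± 3.06 and to 10.6 ± 1.92, 9.15 ± 4.81 and 19.5 ± 13.3 CPM, and Dntt, which marks early lymphoid cells, had 3 counts in CFU-E of FL/FL and 121 in CFU-E of Lepr-Cre mice, a ratio of 41.5, counting interval 13.9 to 204. Dntt did not pass without FL/FL A (adjusted p = 0.0605), FL/FL B (0.115) or FL/FL C (0.0650). T and NK cell markers summed to 4.72 ± 2.33, 4.31 ± 2.97 and 3.63 ± 1.83 CPM in PreCFU-E and to 0.767 ± 0.353, 0.982 ± 1.02 and 2.51 ± 0.912 in CFU-E, neutrophil and monocyte markers to 5.01 ± 1.54, 6.26 ± 1.74 and 3.94 ± 1.13 and to 2.91 ± 1.08, 3.67 ± 1.08 and 2.56 ± 0.357, and mast cell, basophil and eosinophil markers to 12.7 ± 0.686, 15.4 ± 1.18 and 14.1 ± 5.54 and to 9.97 ± 0.923, 13.7 ± 1.12 and 14.4 ± 2.88. Stromal markers, Col1a2 among them, summed to 13.5 ± 3.39, 11.2 ± 3.79 and 19.2 ± 7.02 CPM in PreCFU-E and to 1.34 ± 0.658, 2.21 ± 0.808 and 5.16 ± 1.46 in CFU-E, and endothelial markers to 46.9 ± 4.48, 47.8 ± 14.6 and 26.1 ± 5.21 and to 33.0 ± 4.99, 24.9 ± 6.87 and 11.2 ± 2.54. The 13 mitochondrial genes of the table had 0 counts in every library, so that list could not be read. X- and Y-linked genes had 0 of 4 tested members past the threshold in PreCFU-E of Lepr-Cre against FL/FL mice, each genotype holding 1 female and 2 male mice.

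Genes on the opposite strand overlap Ccnd1, Cish (Gm17040 and Gm17041), Sptb, Add2, Cpox, Fam124a, St3gal6, Pim1, Cdc20, Abcb10, Angpt1, Sox4, Myb, Pfkm, Bcl2, Amigo2, Dedd2, Ccnd2, Shmt2, B3gnt7, Pcdh7, Hspd1, Phldb1, Txnip, St5, Meis1, Coro1a, St8sia6, Lcp2, Kctd12, Kdelc2, Cnn3 and Arpc1b, and the strand setting of the counting is not given in the sources used here, so reads of these pairs cannot be told apart. Globin and histone genes have near-identical copies among which reads could have been split, and Hba-a1, Hbb-bt, Hbb-bs and the histone list are uncertain for that reason.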

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

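The test of a shift along the step to CFU-E, the test of depth in CFU-E of Lepr-Cre B and the spread used to judge the rank of its mouse were chosen only after the result was seen. The genotype effect differed between the 2 cell types, by the interaction test of edgeR, for 38 genes between Lepr-Cre and FL/FL mice, and for 21 without Lepr-Cre A, 23 without Lepr-Cre C and 13 without FL/FL B. The 5 smallest p on each side belonged to Coro1a (7.08 on the log2 scale, a fitted value that rests on 1 count in CFU-E of FL/FL mice), Wdfy4 (2.05), Mef2c (1.86), Abca2 (1.35) and Arpc1b (1.67), and to Sptb (-2.12), Cnn3 (-2.35), Lmna (-1.12), Btnl10 (-1.74) and Hpn (-1.66). Abca2 did not pass without FL/FL B (adjusted p = 0.0629), and Arpc1b did not pass without FL/FL B (0.0691).

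Gene lists also differed between the cell types by camera on the interaction. Between Lepr-Cre and FL/FL mice the median differences were -0.44 for red cell membrane genes, -0.46 for late erythroblast genes, -3.50 for globins, -0.13 for haem synthesis, -0.17 for mitosis, 0.87 for stem and progenitor genes, 0.76 for KIT and ERK targets and 0.31 for glycolysis. Between Lepr-Cre and KO/FL mice they were -0.29 for red cell membrane genes, -0.37 for late erythroblast genes, -0.27 for haem synthesis, -0.15 for S phase, 1.15 for stem and progenitor genes and 0.63 for KIT and ERK targets. Between KO/FL and FL/FL mice red cell membrane genes differed by -0.16. With an estimated correlation, red cell membrane genes held in the first and second (adjusted p = 0.0102 and 0.0350). Stem and progenitor genes held in the second (adjusted p = 0.0350). Hbb-bs, Hba-a2 and Hbb-bt had 0, 1 and 2 counts in PreCFU-E of FL/FL mice, so -3.50 rests on few reads. Dusp6 and Ccnd1, at 0 in PreCFU-E of Lepr-Cre mice, could not fall further.

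Red cell membrane genes rose in PreCFU-E of Lepr-Cre mice, as they did from PreCFU-E to CFU-E. Stem and progenitor genes, which fell in that step, missed the threshold with an estimated correlation there (adjusted p = 0.0634 against FL/FL and 0.0530 against KO/FL mice). Of the genes that changed along that step in FL/FL mice, 74.8% had the same sign in PreCFU-E of Lepr-Cre against KO/FL mice, which share no library with FL/FL (931 rising genes, median 0.18, p = 0.00484, and 997 falling genes, median -0.25, p = 0.0128, by camera with an estimated correlation). If CFU-E cells mixed into the sort were the whole cause, 245 genes lower in CFU-E would need a share of 0.432 (0.396 to 0.472) and 131 genes higher there 0.249 (0.212 to 0.272). The intervals did not overlap, but they resample genes and hold no spread between mice, so a single share is not excluded. At the larger share Egr1, Dusp6, Spry4, Spred1, Spred2, Etv5 and Ccnd1 stood at a median of 0.169 (0 to 0.603) of the mixed level, which decides nothing, since these genes were picked for their fall in the same comparison. PreCFU-E of Lepr-Cre mice may thus be further along the step, and whether the sort gates, admixed CFU-E cells or the genotype placed them there stays open.

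CFU-E of Lepr-Cre B stood apart from the other 8 CFU-E libraries. Depth was argued against, since 43 genes of 3 to 10 CPM had 0 counts in it and at most 6 in the others drawn down to its total of 6804445, or at its own total of 5460920 for FL/FL A. Its squared deviation from its group over the median of the other libraries was 3.65 (3.03 to 4.18) at 3 to 10 CPM and 0.881 (0.809 to 0.945) at 100 CPM and above, so a candidate explanation is fewer starting molecules. PreCFU-E of the same mouse ranked 2 of 9 by deviation (0.252 against 0.256 for the highest), a difference with an interval of -0.0252 to 0.0198, which keeps a state of the whole mouse open. Interferon response genes summed to 787 CPM in PreCFU-E and 636 CPM in CFU-E of this mouse. Lepr-Cre A had 365 and 324 CPM and Lepr-Cre C 398 and 367 CPM. KO/FL B had 743 and 656 CPM, so a high sum was not particular to this mouse.

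A lean of KO/FL mice toward Lepr-Cre mice was tested over sets of genes. Of genes called in PreCFU-E of Lepr-Cre against FL/FL mice, 77.9% had the same sign in CFU-E of KO/FL against FL/FL mice (293 higher, median 0.10, p = 0.0267, and 323 lower, median -0.14, p = 0.0373, by camera with an estimated correlation, and p = 0.0413 and 0.0653 by fry). Genes called in CFU-E had the same sign in PreCFU-E in 65.6% (208 higher, p = 0.0931, and 274 lower, p = 0.251, by camera of limma with an estimated correlation), which leaves PreCFU-E undecided. A partial response to 1 null copy may fit the first value. The 2 cell types of a test share no library but come from the same mice, with FL/FL mice in both comparisons, so the share expected without a response is not known and differences between mice other than the Scf copy stay open.

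Splits of the 6 libraries or mice of a comparison into 3 and 3 number 10, too few for a share under 0.05. The real split alone (1 of 10) gave as many genes in 8 comparisons: Lepr-Cre against FL/FL in PreCFU-E (632 genes, highest other 0) and CFU-E (492 genes, highest other 0), Lepr-Cre against KO/FL in PreCFU-E (225 genes, highest other 3) and CFU-E (103 genes, highest other 6), CFU-E against PreCFU-E in FL/FL (1963 genes, highest other 0), KO/FL (1510 genes, highest other 0) and Lepr-Cre mice (778 genes, highest other 0), and the interaction of Lepr-Cre against FL/FL (38 genes, highest other 0). In the 4 comparisons with 0 calls all 10 splits gave as many by construction, which tests nothing. The highest other was 1 for KO/FL against FL/FL in either cell type and 0 for the other 2 interactions. All other splits placed both genotypes or cell types in each group, which raises the spread, so their few calls say little.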

How the results depend on the processing

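The fit without CFU-E of Lepr-Cre B alone was chosen only after the data were seen. Counts of called genes moved by no more than 1.5 times with DESeq2 size factors, with sex as a covariate, and with the 18 or the 6 libraries of a genotype. Without the filter on low counts edgeR called 394 for Lepr-Cre against KO/FL PreCFU-E, 9 for KO/FL against FL/FL PreCFU-E, 751 for Lepr-Cre against FL/FL CFU-E, 244 for Lepr-Cre against KO/FL CFU-E, 2 for KO/FL against FL/FL CFU-E, 140 for the interaction of Lepr-Cre against FL/FL, 36 for that of Lepr-Cre against KO/FL and 1 for that of KO/FL against FL/FL, from 225, 0, 492, 103, 0, 38, 0 and 0. With DESeq2 the counts were 344 for Lepr-Cre against KO/FL PreCFU-E, 5 for KO/FL against FL/FL PreCFU-E, 755 for Lepr-Cre against FL/FL CFU-E, 229 for Lepr-Cre against KO/FL CFU-E, 1 for KO/FL against FL/FL CFU-E, 102 for the interaction of Lepr-Cre against FL/FL and 23 for that of Lepr-Cre against KO/FL. On log2(RPKM + 1) and log2(RPKM + 0.1) limma called 267 and 263 for Lepr-Cre against FL/FL PreCFU-E, 59 and 64 for Lepr-Cre against KO/FL PreCFU-E, 184 and 194 for Lepr-Cre against FL/FL CFU-E and 29 and 20 for Lepr-Cre against KO/FL CFU-E. Without CFU-E of Lepr-Cre B alone there were 518 genes for the step in Lepr-Cre mice, 50 for the interaction of Lepr-Cre against FL/FL and 3 for that of Lepr-Cre against KO/FL. The cause was not tested for any of these shifts.

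Leaving out 1 library, or 1 mouse for the steps and interactions, gave 371 to 473 genes for Lepr-Cre against FL/FL PreCFU-E, 92 to 218 genes for Lepr-Cre against KO/FL PreCFU-E, 0 to 1 genes for KO/FL against FL/FL PreCFU-E, 226 to 610 genes for Lepr-Cre against FL/FL CFU-E, 19 to 101 genes for Lepr-Cre against KO/FL CFU-E and 0 to 1 genes for KO/FL against FL/FL CFU-E. It gave 929 to 1371 for the step in FL/FL, 859 to 996 for the step in KO/FL, 362 to 543 for the step in Lepr-Cre mice, 13 to 43 for the interaction of Lepr-Cre against FL/FL, 0 to 2 for that of Lepr-Cre against KO/FL and 0 to 0 for that of KO/FL against FL/FL, with fewer libraries and so less power in each such fit. A group left with 2 libraries was assumed to vary like the others.

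With the replicate letter as a block, edgeR called 1586 genes for Lepr-Cre against FL/FL PreCFU-E (856 higher and 730 lower), 840 for Lepr-Cre against KO/FL PreCFU-E, 9 for KO/FL against FL/FL PreCFU-E (Sptb, Ptger3 and Pim1 among them, adjusted p = 3.68e-06, 0.00200 and 0.0105), 933 for Lepr-Cre against FL/FL CFU-E and 280 for Lepr-Cre against KO/FL CFU-E. All 3 letter correlations passed 0.1 in the second of these alone. The others had 0.09997 to 0.131, 0.0916 to 0.141, 0.0803 to 0.125 and 0.0873 to 0.154. Each library correlated best with its own letter in 3 of 3 pairs, so a pairing stays open in each. With the mouse as a block the counts were 1322 for the step in Lepr-Cre mice, 198 for the interaction of Lepr-Cre against FL/FL and 61 for that of Lepr-Cre against KO/FL. Camera with the block called 5 lists for KO/FL against FL/FL CFU-E and 3 for the interaction of KO/FL against FL/FL, from 3 and 1. The block moved no other count of genes or lists by over 1.5 times, and among named genes it ended 3 calls and added 8.

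Gene list calls fell most where the inter-gene correlation was estimated from the data, tied with fry where KO/FL and FL/FL mice were compared. They fell to 4 for Lepr-Cre against FL/FL PreCFU-E, 2 for Lepr-Cre against KO/FL PreCFU-E, 0 for KO/FL against FL/FL PreCFU-E, 0 for Lepr-Cre against FL/FL CFU-E, 1 for Lepr-Cre against KO/FL CFU-E and 0 for KO/FL against FL/FL CFU-E. For the step in FL/FL and in KO/FL they fell to 8 and 8, and for the 3 interactions, in the order above, to 1, 2 and 0. An estimated correlation above the preset 0.01 widens the test by its construction. With fry, which does not compare a list with other genes, 10 lists passed for Lepr-Cre against KO/FL PreCFU-E, 0 for KO/FL against FL/FL PreCFU-E, 4 for Lepr-Cre against FL/FL CFU-E, 4 for Lepr-Cre against KO/FL CFU-E, 0 for KO/FL against FL/FL CFU-E, 3 for the interaction of Lepr-Cre against FL/FL and 0 for that of KO/FL against FL/FL. DESeq2 size factors moved no list count by over 1.5 times.

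For named genes, 3936 log2 fold changes were recomputed with all libraries. Of these 3609 kept their direction and side of the threshold, 298 lost a call, 128 and 121 of them on the 2 RPKM scales, 29 gained one and 0 changed sign. With 1 library or mouse left out, 1982 of 2473 kept both, 487 lost a call, 3 gained one and 1 changed sign, the interaction of KO/FL against FL/FL for Kit, not called, which was -0.067 without FL/FL B against 0.04 and 0.113 without FL/FL A. Dusp6 in the step in Lepr-Cre mice gave no value without Lepr-Cre A, where both groups were at 0. Depth limits genes under about 3 counts per group, such as Kitl, to a floor.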

Other observations

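The test of the RPKM divisors was chosen only after the result was seen. Globin genes, which are induced late in erythroid maturation, summed to 1.15 ± 1.52, 1.49 ± 1.19 and 9.91 ± 4.01 CPM in PreCFU-E of FL/FL, KO/FL and Lepr-Cre mice and to 31.9 ± 6.46, 29.0 ± 7.62 and 64.0 ± 23.2 CPM in CFU-E. Stem and progenitor genes summed to 710.4 ± 45.5, 695 ± 23.7 and 474 ± 94.0 CPM in PreCFU-E and to 395 ± 59.9, 337 ± 46.8 and 328 ± 48.8 in CFU-E, in the same order, and megakaryocyte genes to 189.8 ± 12.5, 183 ± 8.92 and 152 ± 8.82 and to 157 ± 15.5, 136 ± 18.7 and 119 ± 12.2.

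The deposited RPKM values imply 1 divisor per gene. Of 15400 genes compared with GENCODE M21, the divisor equalled the gene's own span in 3.07% (473 genes). It equalled the span of a gene 1 to 20 places further on in the table in 77.7% (11963 genes), against 0.0260% (4 genes) where the window was moved 1000 places on. RPKM of different genes are therefore not comparable with one another, while a gene's fold change between libraries does not depend on its divisor apart from the pseudocount.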
